A study of Caenorhabditis elegans with 2 samples.

How the data were processed

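Chromatin immunoprecipitation with an anti-GFP antibody and sequencing was done on 2 biological replicates of whole late embryos of 1 strain, per the labels. Chromatin was sonicated, with fragments of 200 to 800 bp, per the labels. The replicates formed 1 group, and the labels name no second condition, so comparisons were made between the replicates and between kinds of regions.

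Per the submitters' file manifests, each replicate's list of 30000 candidate regions came from that replicate's alignments and 1 control library, the pooled list from both replicates' alignments and the same control, and the optimal set from these 3 lists by the irreproducible discovery rate (IDR). The assembly is ce11, per the labels. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited files hold a signal value per region, the authors' own measure of enrichment over the control, whose scale is not given in the sources used here. They also hold −log10 q-values as deposited by the authors, which reach at most 2.36 in the pooled list and are equal at that maximum for 114 regions, so they were not used to rank. Signal values were used to rank regions within a list, to describe them and to correlate the replicates; no difference in signal between lists was tested. The candidate lists hold background regions by design: of the pooled 30000, 251 had a −log10 q of at least 2 in the deposited list. It was checked on the files that the optimal set equals the 423 pooled candidates of highest signal. Regions were 370 bp wide at most in the pooled list, and 77 optimal peaks were narrower. Lists of regions carry no read counts, so the depth of each library was unknown, and intervals on shares cover the number of regions only.

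Genes came from Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence from the RefSeq copy of that assembly. Names of non-coding genes and tRNA amino acids came from RefSeq by gene identifier; 26914 of 26917 non-coding genes had the same coordinates in both. A region was placed by its summit. The promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated protein-coding transcript start; many annotated starts in this species are sites of trans-splicing, so true starts can lie further upstream. A region was called at a non-coding gene if the summit lay in it or within 100 bp. The 6 classes considered for peaks at no annotated non-coding gene were tRNA, tRNA pseudogene, snoRNA, snRNA, miRNA and other ncRNA.

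Shares were compared by Fisher's exact test, two-sided, with conditional odds ratios and 95% intervals, and shares have 95% Wilson intervals. The background was the other pooled candidates, which are regions that could have been kept. Regions are not replicates, so these tests describe this set of regions and not the spread between embryo preparations. Motifs within 50 bp of the summit were compared with flanks of the same peaks centred 400 bp away on each side. McNemar's exact test had been planned; it was extended to both flanks at once, as a matched exact test, after the data had been seen, and each flank alone was run as an alternative. Gene lists, the tests of the planned comparisons, and the rule for named genes were fixed before the data were examined. The rule took the nearest protein-coding start to each of the 25 optimal peaks of highest signal, any second gene whose promoter window held the summit, up to 4 members of each list with the highest signal, and 8 genes named in advance. 1 list member, the microRNA gene lsy-6, matched no protein-coding gene. Benjamini-Hochberg adjustment was applied over 10 E-boxes, 2080 6-mers, 28 lists, 6 nuclear chromosomes, 4 gene parts, 11 non-coding classes and 15 comparisons of boxes, at 0.05. Overlap of replicates was tested against 1000 random draws with a fixed seed. The bounds used to judge a changed Spearman correlation came from 1000 bootstrap samples of peaks.

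The uniqueness of sequence was measured as the share of 32-mers within 50 bp of a summit that occur once in the genome on either strand. Odds ratios adjusted for base composition were Mantel-Haenszel estimates over 10 strata of G+C content.

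Motif and list tests were tested on simulated data first. With an E-box planted in 25% of 423 simulated centres the E-box test called 1 motif with it and 0 without, the scan called 7 overlapping 6-mers and 0, and the list test called 2 planted lists of 28 and 0. Simulated centres and flanks had the same base composition, unlike the real ones. The simulation therefore did not check for calls caused by a difference in G+C content between summits and flanks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

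Alternatives planned in advance were a stricter set (the better 50% of optimal peaks), each replicate alone, other overlap rules, other promoter and motif windows, other flanks, other backgrounds and other widths around hlh-13. Added after seeing the data were the non-coding gene classes with their alternatives, all that rests on these classes (shares by rank, distances of summits, A and B boxes, tRNA genes on X), each flank alone, and each comparison without peaks at tRNA, snoRNA and snRNA genes. Input or control region lists and other factors were not analysed here.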

Results

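Chromatin from whole late embryos of Caenorhabditis elegans was immunoprecipitated with an antibody against GFP and sequenced. The worms carried a transgene with the gene hlh-13, which encodes a basic helix-loop-helix transcription factor of the Ptf1a family, fused at its 3' end to GFP and FLAG tags. The embryos came from strain OP744, were obtained by egg bleaching, pooled both sexes and were 3.5 hours old. The series held 1 group of 2 biological replicates, so its design asks where in the genome the tagged protein was recovered and how far the replicates matched. For each replicate and for the pooled reads the authors deposited 30000 candidate regions, and they kept 423 of them as the optimal set by the irreproducible discovery rate. These were the 423 pooled regions with the highest signal value, from 85.3 to 668, against a median of 34.2 over all pooled candidates. Read depth was unknown, because the lists held regions and no read counts. Coordinates are 1-based on ce11 (WBcel235).

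Which genes lay under the summits was asked first. Genes for small structured RNAs led the optimal set. A tRNA gene lay within 100 bp of the summit in 152 of the 423 optimal peaks (35.9%, 95% Wilson interval 31.5 to 40.6%), against 185 of the other 29577 candidates (0.625%, 0.542 to 0.722%). The odds ratio was 89 (95% interval 69.1 to 114.7, Fisher's exact test, two-sided, adjusted p = 1.07e-195). Genes for snoRNAs, which guide the modification of other RNAs, lay at 49 optimal peaks (11.6%, interval 8.87 to 15%) and at 0.243% of the other candidates, with an odds ratio of 53.6 (36 to 79.4, adjusted exact p = 3.88e-58). Genes annotated as snRNAs lay at 6 optimal peaks (1.42%) and at 0.0676% of the others, with an odds ratio of 21.3 (6.95 to 55.2, adjusted exact p = 3.78e-06). Of these 6 peaks, 4 lay at sls-2 genes, which encode SL2 spliced leader RNAs, and 2 at genes with the ACAGAGA box of the spliceosomal U6 RNA, a split made after the names were seen. Together these 3 classes accounted for 207 optimal peaks (48.9%, 44.2 to 53.7%). Other annotated ncRNA genes were also enriched, at 147 optimal peaks (34.8% against 5.35%, odds ratio 9.42, 7.61 to 11.6, adjusted exact p = 4.96e-74). Of these 147 peaks, 31 lay at no gene of the 3 classes above; without peaks at those classes the odds ratio was 3.21 (2.11 to 4.74). Pseudogenes of tRNA genes (odds ratio 5.70, adjusted exact p = 0.0343) and miRNA genes (5.02, adjusted exact p = 0.0401) passed with 3 optimal peaks each. Of the 3 peaks at tRNA pseudogenes, 2 also lay at a gene of the 3 classes above. Without peaks at those classes 1 was left, with an odds ratio of 3.78 (0.0927 to 22.7, unadjusted exact p = 0.238). For miRNA genes all 3 were left, with an odds ratio of 9.81 (1.93 to 31.1). Pseudogenes of protein-coding genes went the other way, with 1 optimal peak (0.236%) against 2.01% of the candidates (odds ratio 0.115, adjusted exact p = 0.00902). No summit of any pooled candidate lay within 100 bp of the 20 annotated rRNA genes. No optimal peak could therefore lie there, and recovery of rRNA genes could not be judged. Against the 423 candidates ranked just below the optimal set the odds ratio was 5.84 for tRNA genes and 10.9 for snoRNA genes, and 2.01 for snRNA genes, which no longer passed (exact p = 0.505). With only summits inside the gene it was 84.7 for tRNA genes, 10.1 for snoRNA genes and 14 for snRNA genes (2 optimal peaks). These gene classes were looked at after the 6-mers at the summits had been seen.

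The share fell steeply along the ranked list. Among the 100 pooled regions of highest signal, 40 lay at a tRNA gene and 33 at a snoRNA gene. In the other optimal peaks tRNA genes were at 34.7% and snoRNA genes at 4.95%. From rank 424 to 1000 these values were 8.15% and 1.39%, and from rank 10001 to 30000 they were 0.240% and 0.170%. Optimal peaks lay at 157 of the 612 annotated tRNA genes (25.7%), at 50 of the 346 snoRNA genes (14.5%) and at 6 snRNA genes (4.65%). Among as many best regions of each replicate alone, 133 tRNA genes had a region in replicate 1 and 140 in replicate 2, and 105 tRNA genes were common to both.

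**Figure D1:**
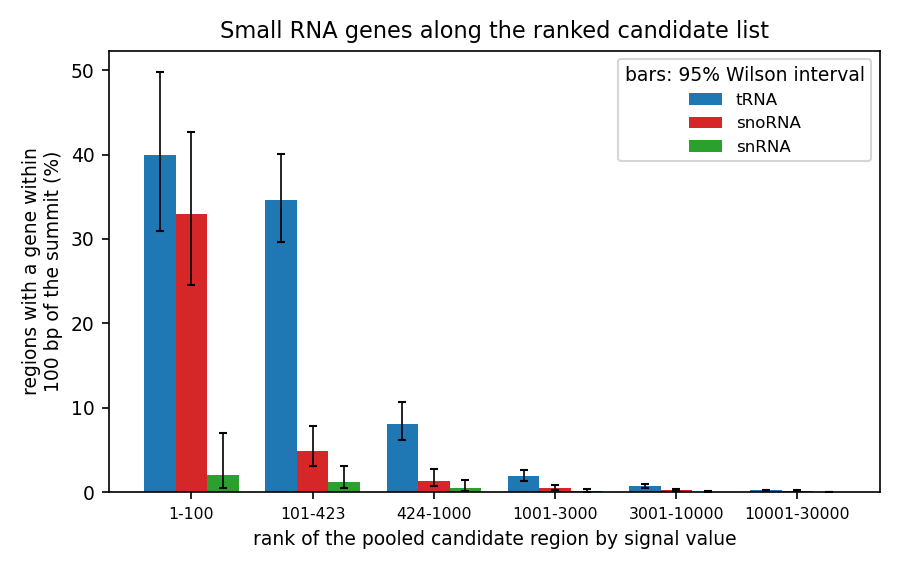
Share of pooled candidate regions (y axis, percent) with a tRNA, snoRNA or snRNA gene within 100 bp of the summit, by rank of signal value (x axis, rank 1 is the highest); bars are shares and whiskers 95% Wilson intervals. tRNA genes went from 40% of the 100 best regions to 0.240% of ranks 10001 to 30000.

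The summits sat at different places relative to the RNA classes. At tRNA genes the median summit was 14 bp inside the gene from its 5' end, and the median length of tRNA genes was 72 bp. At snoRNA genes 45 of 49 summits (91.8%) lay upstream of the gene, at a median of 44 bp (quartiles 27 and 58 bp). The B box (RGTTCRANNCC) and the A box (TRGYNNARNNG) are promoter elements inside tRNA genes that bind the RNA polymerase III factor TFIIIC. Within 100 bp of the summit both boxes were present in 117 of the 152 peaks at tRNA genes (77%), against 1.64% of their flanks at 500 bp. Since the boxes are part of tRNA genes, many other candidates at such genes had both, 126 of 185 (68.1%; odds ratio 1.56, 95% interval 0.936 to 2.64, adjusted exact p = 0.146). The A box by itself differed, with 150 of 152 (98.7%) against 166 of 185 (89.7%; odds ratio 8.54, 2.01 to 76.9, adjusted exact p = 0.00103). The summit lay inside the gene in 93 of these 152 and 98 of these 185. A summit further from the gene can leave a box outside the searched window, and this was not adjusted for. Both boxes were present in 15 of the 49 peaks at snoRNA genes (30.6%), where the flanks had 0% and other candidates at snoRNA genes 1.39% (odds ratio 30.5, 95% interval 4.36 to 1337, Fisher's exact test, two-sided, adjusted p = 8.16e-06). At snoRNA genes 3 optimal summits and 21 others lay inside the gene, so the place of the summit can affect this comparison too. At the 183 optimal peaks near no annotated non-coding gene of the 6 classes considered, both boxes were found in 2 peaks (1.09%), against 0.446% of comparable candidates (odds ratio 2.46, 0.293 to 9.22, adjusted exact p = 0.250). The boxes and the distances were chosen after the 6-mers had been seen.

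The 25 peaks of highest signal, from 284 to 668, had a tRNA, snoRNA or snRNA gene within 100 bp in 18 cases. The peak of highest signal (V, 12303481 to 12303798, summit 12303639, signal 668) lay in an intron at the snoRNA genes C51F7.3 and C51F7.4, 1098 bp downstream of the nearest protein-coding start, that of F55C5.17. The next (II, 11960667 to 11960976, signal 616) was intergenic at the snoRNA gene W03C9.9, with W03C9.1 as the nearest coding gene. Further down came sup-5, a tRNA-Trp gene known for its amber suppressor alleles (III, summit 8678562, signal 297), and mir-51, a microRNA gene (IV, summit 11026189, signal 337). In 8 of the 25 peaks the summit lay in a promoter window. The genes were K12H4.5, sre-23, the pair ears-2 and uncp-18, the pair C28G1.2 and sec-15, T13C5.6, cfim-2, M01F1.9 and the pair F55A11.6 and F55A11.11. Of these, ears-2, which encodes a glutamyl-tRNA synthetase, had its start 40 bp from the summit (IV, 390508, signal 330). For the other peaks the nearest protein-coding starts were those of F55C5.17, W03C9.1, pxn-1, cutl-18, nas-30, str-56, wht-2, C04A11.5, hrg-5, Y43F8C.7, col-94, cec-4, fbxa-55, mpk-2, pgl-2, col-85 and pdl-1. Over all 25 the distance to the nearest start ranged from 40 to 5699 bp. The peaks nearest nas-30 (I, summit 933517) and fbxa-55 (III, summit 931606) lay on repeated sequence, where 67.1% and 27.1% of the 32-mers within 50 bp of the summit occurred once in the genome. The share was under 100% in 8 of the 25 peaks, among them 57.1% at sup-5 and 50% at C28G1.2, and was 100% at the peaks of rank 1 to 6.

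How far the replicates matched was asked next. Of the 423 best regions of replicate 1, 248 overlapped one of the 423 best of replicate 2 by at least 1 bp (58.6%, Wilson interval 53.9 to 63.2%). In 1000 random draws of 423 regions from the candidates of replicate 2 the mean was 1.47% and the highest value 3.55% (permutation test, one-sided, p = 0.001, the smallest these draws can give). The share depended on the cutoff: it was 75.8% for the 211 best regions of each replicate and 43.7% for the 846 best. Regions of replicate 1 and replicate 2 were called against the same control library, which can raise the overlap, and this could not be simulated from region lists. Across the 422 optimal peaks with a candidate in both replicates the signal values had a Spearman correlation of 0.605 and a Pearson correlation of 0.866. These are across regions, which are not independent replicates. Without peaks at tRNA, snoRNA and snRNA genes the Spearman value was 0.357 over 215 peaks. Optimal peaks had been selected from these same lists for reproducibility and had the highest pooled signal, which affects such values. Not every optimal peak ranked high in both replicates. Of the 423, 319 overlapped one of the 423 best regions of replicate 1, 325 one of replicate 2 and 244 one of each. At the optimal peak near exos-8 (II, summit 6741584) the best candidate ranked 10034 in replicate 1 and 188 in replicate 2. Over 13315 pooled candidates with a value in both replicates the Spearman value was 0.243. The excess of tRNA genes was present in each replicate, with odds ratios of 61.0 in replicate 1 and 70.9 in replicate 2, that of snoRNA genes with 46 and 53.7, and that of snRNA genes with 14.1 and 17.7 on 5 peaks each.

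Where the peaks lay relative to protein-coding genes was compared with the other candidates. Optimal summits avoided coding exons: 9 of 423 (2.13%) lay in one, against 29.3% of other candidates (odds ratio 0.0524, 95% interval 0.0238 to 0.101, Fisher's exact test, two-sided, adjusted p = 1.74e-48). They were intergenic in 60% against 33.4% (odds ratio 3.00, 2.45 to 3.67, adjusted exact p = 2.35e-28), and intronic in 35.5% against 32% (adjusted exact p = 0.142). Summits within 1000 bp upstream to 200 bp downstream of a protein-coding start made up 193 of 423 (45.6%, interval 40.9 to 50.4%) against 29.6% (odds ratio 2.00, 1.64 to 2.43, exact p = 6.46e-12). The regions of highest signal did not share this excess: the share was 27% in the 100 best and 51.4% in the other optimal peaks. It was 45.4% from rank 424 to 1000 and 28.3% from rank 10001 to 30000. Away from tRNA, snoRNA and snRNA genes the share was 137 of 216 (63.4%, 56.8 to 69.6%; odds ratio 4.12). Against the 423 candidates ranked just below the optimal set, of which 47% lay in that window, the direction turned (odds ratio 0.945, 0.714 to 1.25, exact p = 0.730).

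Protein-coding genes with an optimal peak in the promoter window numbered 264, of 7662 with any pooled candidate there, and 28 gene lists were tested among them. The ribosomal protein genes were the 1 list that passed: 11 of 60 had an optimal peak (18.3%), where 2.07 were expected (odds ratio 6.52, 95% interval 3.02 to 12.9, Fisher's exact test, two-sided, adjusted p = 0.000141). None of these 11 peaks lay at a tRNA, snoRNA or snRNA gene, and their summits were 31 to 761 bp upstream of the start, with a median of 279 bp. Another gene had the nearer start at 4 of them: hsr-9 for rps-19, Y17G9B.5 for rpl-20, ekl-4 for rps-20 and Y48B6A.1 for rpl-43. With the nearest start within 5 kb the count was 7 of 56 (odds ratio 4.53, 1.72 to 10.2, adjusted exact p = 0.0455), and with all protein-coding genes as background the odds ratio was 12.7. The highest was at rpl-3 (III, summit 3867575, rank 76, signal 196, 279 bp upstream), followed by rps-19 (I, 9626059, signal 134), rpl-20 (IV, 4750064, signal 133) and rps-23 (IV, 12391319, signal 125). In the better 50% of the optimal peaks 5 of 57 had one, with an odds ratio of 6.24 (1.91 to 15.9), and the call was lost (adjusted exact p = 0.0537).

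In 20 of the 28 lists, most of the neuronal and cell fate lists among them, no member had an optimal peak in the promoter window. Of the genes with a candidate region, 0 of 18 bHLH factors had one (0.620 expected, upper bound of the odds ratio 6.40), 0 of 25 neuronal terminal selectors (upper bound 4.47), 0 of 22 pan-neuronal genes (5.13), 0 of 50 neuropeptide genes (2.15) and 0 of 27 axon guidance genes (4.11). The count was also 0 for 4 monoamine, 5 GABA and 6 cholinergic or glutamatergic neuron genes, 33 ceh homeobox genes, 5 Hox genes and cofactors and 13 Notch and Wnt genes. It was 0 for the lists of 9 glia, 24 hypodermis, 10 pharynx and 9 intestine genes, 19 histones, 17 innexins, 4 cadherins, 9 tubulins and actins and 2 major sperm proteins. These lists are short, and the upper bounds leave room for enrichment by several fold in most of them. The zeros were not stable: under some alternative rule 11 of these 20 lists had a member with a peak. With the nearest start within 5 kb, 4 of 89 neuropeptide genes had one (2.76 expected), and with replicate 1 alone 1 of 19 bHLH factors. None of these passed (lowest adjusted exact p = 0.480). In the remaining lists a few members had a peak without passing the test. They were 1 of 29 body wall muscle genes (unc-98), 1 of 18 ciliated sensory genes (daf-19, the RFX factor of ciliated neurons), 1 of 43 collagens (col-185) and 1 of 11 germline genes (mex-1). There were also 2 of 35 heat shock genes (dnj-29 and hsp-60), 2 of 88 nuclear hormone receptors (nhr-255 and nhr-41) and 6 of 205 chemoreceptors (sre-23, sre-1, srh-269 and sre-47 had the highest signal). The peaks at sre-23, srh-269, col-185, nhr-255 and nhr-41 each lay at a tRNA or snoRNA gene.

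For genes of the aminergic, GABA and glutamate neurons named before the data were examined, tbh-1, unc-25 and eat-4 had no pooled candidate in the promoter window. The best candidates of unc-47, the vesicular GABA transporter gene (III, summit 10186911), and of tdc-1, tyrosine decarboxylase (II, summit 8270692), ranked 8967 and 15369 with signals of 40.1 and 33.9. For hlh-2, the gene of the bHLH partner protein, the best candidate ranked 23278 (I, summit 7194121, signal 28.9).

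Basic helix-loop-helix dimers bind E-boxes (CANNTG), so E-boxes within 50 bp of the summits were compared with flanks of the same peaks at 400 bp. Any E-box was present in 134 of 423 peaks (31.7%), with 30.4% in the flanks (matched exact test, two-sided, p = 0.645) and 35.0% in other candidates. Of the 10 E-boxes, CACATG was more frequent at the summit, in 26 peaks against a mean of 10 in the flanks (6.15% against 2.36%, adjusted exact p = 0.00847), and CAAATG was less frequent, in 20 against 37 (adjusted exact p = 0.0389). CAAGTG was in 29 against 15.5 (adjusted exact p = 0.0570). CAGCTG was in 11 against 6 (adjusted exact p = 0.432) and CAGATG in 10 against 14.5 (adjusted exact p = 0.487). Against the other candidates CACATG was also more frequent (3.71% there, odds ratio 1.70, adjusted exact p = 0.0449). CAAATG was less frequent (4.73% against 8.75%, odds ratio 0.518, adjusted exact p = 0.0226), and so was CAGATG (2.36% against 5.01%, odds ratio 0.459, adjusted exact p = 0.0449).

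The E-box calls against the flanks changed with the settings. Without peaks at tRNA, snoRNA and snRNA genes the CACATG excess was gone, with 5 peaks against 4.5. In 4 other settings the call was lost while the excess stayed: 15 against 6.5 in the better 50% of peaks, 26 against 11.5 with flanks at 250 bp, 26 against 16 with flanks at 800 bp and 26 against 15 on the left flank alone. CAAATG stayed below the flanks in all 10 alternatives, but the call was lost in 8. The counts there were 26 against 31 in replicate 1 alone, 18 against 29.5 in replicate 2 alone, 9 against 15.5 in the better 50% and 9 against 19 without peaks at those genes. They were 9 against 16.5 within 25 bp, 51 against 73 within 100 bp, 20 against 30.5 with flanks at 250 bp and 20 against 33 on the left flank alone. The call stayed with flanks at 800 bp (20 against 45.5) and on the right flank alone (20 against 41).

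Without assuming the E-box, 498 of 2080 strand-collapsed 6-mers were more frequent at the summits than in the flanks and 340 were less frequent (matched exact test, two-sided, adjusted p under 0.05). The leading ones were CGAACC in 74 peaks against 8, ACCACT in 87 against 14 and GTTCGA in 89 against 17. GTTCGA is the core of the B box, and CGAACC, which reads GGTTCG on the other strand, overlaps it there. Such 6-mers are therefore not separate motifs. AT-rich 6-mers were depleted, with AAAAAT in 68 against 198.5. Among the 216 optimal peaks away from tRNA, snoRNA and snRNA genes, 160 were more frequent, led by GCGCAC in 40 peaks against 4 and CGCACA in 39 against 3.5. The G+C content within 50 bp of the summit was 50.5% ± 6.95 (SD over 423 peaks), against 41.7% ± 8.60 in the other candidates. In the flanks at 400 bp the mean was 36.1% on one side and 35.2% on the other. Comparisons with the flanks, of 6-mers and of E-boxes such as CAAATG, therefore do not separate motifs from base composition. How much of the 6-mer counts base composition accounts for was not tested.

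**Figure D2:**
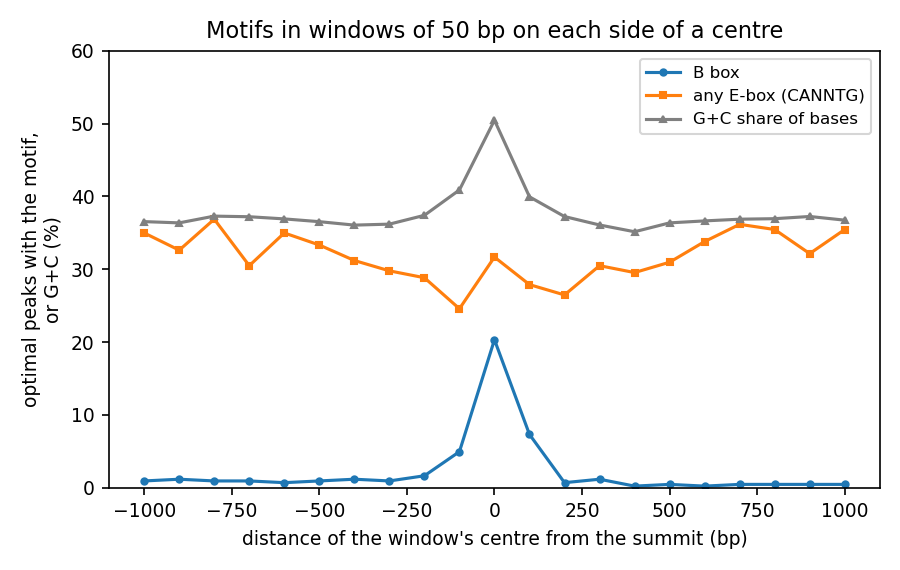
Share of the 423 optimal peaks (y axis, percent) with a B box or any E-box, and the mean G+C share of bases, in windows of 50 bp on each side of centres at distances up to 1000 bp on each side of the summit (x axis). The B box rose to 20.3% and G+C to 50.5% at the summit, where E-boxes were at 31.7%.

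The X chromosome held more of the optimal peaks than of the other candidates, 107 of 423 (25.3%, interval 21.4 to 29.6%) against 16.4% (odds ratio 1.73, 95% interval 1.37 to 2.16, Fisher's exact test, two-sided, adjusted p = 2.06e-05). None of chromosomes I to V passed (lowest adjusted exact p = 0.0987, for II and V). Of the 157 tRNA genes with an optimal peak 46.5% were on X, as were 45.1% of all annotated tRNA genes. A tRNA gene on X had an optimal peak as often as one on an autosome within the error (26.4% against 25%, odds ratio 1.08, 0.737 to 1.58, exact p = 0.710). Without peaks at tRNA, snoRNA and snRNA genes the odds ratio for X was 1.03 (0.697 to 1.48, exact p = 0.853).

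The transgene adds copies of hlh-13 and of the rescue gene unc-119, so regions near both genes were counted. No optimal peak lay within 20 kb of hlh-13 (X, 4249249 to 4250766). The best pooled candidate there ranked 552 (summit 4246486, signal 77.9), and the candidate in the promoter window, in a coding exon, ranked 19688 (summit 4249432, signal 31.0). The 40 kb held 17 pooled candidates against a median of 12 over 5004 such windows, and 1081 windows held as many or more. In replicate 1 the count was 21, reached by 288 windows, and in replicate 2 it was 12, reached by 2611. Within 40 kb there were 2 optimal peaks, of which the higher (X, summit 4222503, rank 241, signal 107) lay at the snoRNA gene W01H2.11. Near unc-119 (III, 10902641 to 10908935) no optimal peak lay within 40 kb, and 18 pooled candidates lay within 20 kb, a count reached by 864 windows. The best candidate in its promoter window ranked 13797 (summit 10907039, signal 35.2).

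**Figure D3:**
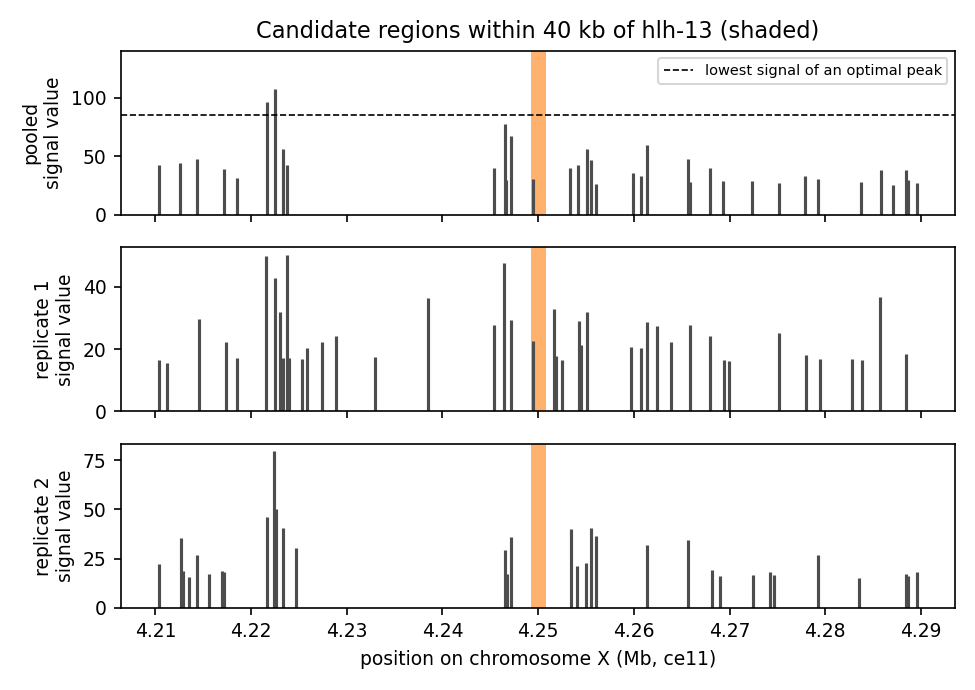
Signal value (y axis, no unit) of each candidate region within 40 kb of hlh-13, at its summit position on chromosome X in Mb on ce11 (x axis), in the pooled list and in each replicate; the shaded bar is hlh-13. The dashed line in the pooled panel is the lowest signal of an optimal peak, 85.3, which 2 regions upstream of the gene exceeded.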

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

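The tRNA, snoRNA and snRNA comparisons, the runs without peaks at those genes and the runs with each flank alone were chosen after seeing the data; the other alternatives were planned. Of 73 alternatives to 13 results, 57 kept direction and call, or stayed within the error or near the main count. E-boxes were counted here by those more frequent at the summit. Overlap of the replicates counted as kept by its permutation test alone, although the share was 75.8% for the 211 best regions and 43.7% for the 846 best. The 57 also hold 6-mer counts of 389 and 434 in replicate 1 and replicate 2 alone and 537 within 100 bp, against 498. The odds ratio for promoters turned to 0.945 against the 423 candidates ranked just below the optimal set. The odds ratio for snRNA genes against those candidates was 2.01 and no longer passed. The Spearman correlation of the replicates was 0.243 over all pooled candidates with a value in both, 0.726 in the better 50% of optimal peaks and 0.357 without peaks at tRNA, snoRNA and snRNA genes. The number of E-boxes more frequent at the summit went from 1 to 0 in the better 50%, without those genes, with flanks at 250 bp, with flanks at 800 bp and against the left flank alone, and to 2 against the right flank alone. The less frequent CAAATG lost its call in 8 of 10 alternatives, of which 4 are among the 57, but stayed below the flanks in all 10. The number of 6-mers went from 498 to 326 in the better 50% and to 160 without those genes; both sets hold fewer peaks. The number of gene lists went from 1 to 0 in the better 50%, where the odds ratio of ribosomal protein genes was 6.24 against 6.52. The odds ratio for X went to 1.03 without those genes, and the number of optimal peaks near hlh-13 from 0 to 2 at 40 kb on each side, a wider window. Where no value above or the construction of the alternative shows it, the cause was not tested. With replicate 1 or replicate 2 alone, the odds ratios of tRNA genes were 61.0 and 70.9, and those of promoters 1.99 and 1.85. Depth was unknown, so its effect on the number of peaks was not measured. No paired analysis was possible because there was 1 group.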

Other observations

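The tests in this part on RNA polymerase III genes, on tRNA amino acids, and on each E-box apart were chosen after the results had been seen. Other genes known to be transcribed by RNA polymerase III were among the optimal peaks. The gene of the RNase P RNA, rpr-1 (I, 13463955 to 13464207), had the peak of rank 34 with a signal of 253, 135 in replicate 1 and 113 in replicate 2. The gene of the RNase MRP RNA, mrpr-1 (II, 7200233 to 7200418), had the peak of rank 32 with a signal of 256, 133 and 125 in the replicates. Optimal peaks also lay at the signal recognition particle RNA genes srpr-2.2 (rank 88, signal 185), srpr-1.2 (rank 204, signal 117) and srpr-2.1 (rank 313, signal 97.2). Their sequence is largely repeated: 24.3%, 0% and 11.4% of the 32-mers within 50 bp of these summits occurred once in the genome. The Y RNA gene yrn-1 (IV, 7499508 to 7499612) had no pooled candidate within 100 bp. Neither had the non-coding RNA gene rncs-1 (X, 1011501 to 1012347), whose polymerase is not given in the sources used here. Of 22 snRNA genes that hold the ACAGAGA box of U6, 2 had an optimal peak and 5 a pooled candidate, against 4 and 20 of the other 107 snRNA genes.

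Optimal peaks were spread over the tRNA amino acids. Of 607 tRNA genes with an amino acid in the annotation, those for phenylalanine had an optimal peak most often (6 of 14, 42.9%), followed by cysteine (5 of 13, 38.5%) and alanine (13 of 34, 38.2%). Those for histidine (3 of 20, 15%) and tryptophan (2 of 12, 16.7%) had one least often apart from the single selenocysteine gene, which had 0. None of the 21 groups passed Fisher's exact test against the other tRNA genes after Benjamini-Hochberg adjustment (lowest unadjusted p = 0.104).

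The recovery of tRNA genes was set against 3 technical explanations. Reads shared between near-identical copies are not the whole cause: among regions with only unique 32-mers near the summit the odds ratio for a tRNA gene was 48.4 (95% interval 28.5 to 80.0), although only 25 of the 152 peaks at tRNA genes met that condition and the others remain untested. Base composition is not the whole cause either, with an odds ratio of 50.1 (38.4 to 65.4) over strata of G+C content. A general pull-down of highly transcribed genes stays open: promoters of ribosomal protein genes were also enriched, with an odds ratio of 6.52 (3.02 to 12.9), which this explanation needs. That this lay below the tRNA value had been set in advance as counting against it, but one ratio is over genes and the other over regions, so their sizes cannot be compared. No biological explanation was tested, since the series has 1 group; binding of HLH-13 at these genes, recovery of open chromatin by the antibody and a wrong label cannot be told apart without a pull-down from untagged worms, which was not analysed here.

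The excess of optimal peaks on X is consistent with the position of tRNA and other small RNA genes, since without peaks at such genes the odds ratio for X was 1.03 (0.697 to 1.48), and 45.1% of tRNA genes are on X. The interval leaves room for a moderate excess.

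The E-boxes CACATG and CAAGTG were weighed against the sequence of small RNA genes. Without peaks at tRNA, snoRNA and snRNA genes, the excess of CACATG peaks over the flanks went from 16 to 0.5 (matched exact test p = 1), so tRNA and other small RNA gene sequence is a candidate explanation for the CACATG part. The excess of CAAGTG went from 13.5 to 10 (matched exact test p = 0.0183, 0.163 after adjustment over the 10 E-boxes and 0.0366 over these 2 motifs only). Over all peaks the adjusted exact value of CAAGTG was 0.0570 on both flanks, 0.0384 on the right flank alone and 0.537 on the left flank alone (29 against 19). It was 0.369 in replicate 1 alone, 0.364 in replicate 2 alone and 0.496 within 100 bp. The right flank alone was the only alternative in which CAAGTG passed. The motif was picked after its result was seen and did not pass over the 10 E-boxes with both flanks, so whether small RNA gene sequence is the cause of the CAAGTG part stays open. The rule for these 2 motifs was set to the adjusted value after the values were known. For having either motif, the odds ratio against other candidates over strata of G+C content was 1.45 (1.08 to 1.94). Base composition as the cause had been set to need an interval that reaches 1, which was not found. Its exclusion needed a higher lower bound than was found, so it stays open. This ratio does not bear on the excess over the flanks.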
